A study of Mus musculus with 23 samples.

How the data were processed

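Gene-level quantification of 23 mouse heart libraries in 6 groups was analysed. Per the file headers, the authors deposited 1 file per library with estimated counts of reads per gene, TPM (a length-scaled abundance, already divided by effective length) and the effective gene length in bases, another quantity that was used for offsets alone. The submitters' processing notes name bcl2fastq, DRAGEN, edgeR and limma and the mm10 build, without versions, and the annotation release and read strand setting are not given in the sources used here. In the files, 9.50% of all values, zeros included, were not whole, so the deposited estimated counts were rounded before testing. Of 55487 gene identifiers, 55141 matched GENCODE M21 (GRCm38, the assembly of mm10) once versions were removed, and symbols and coordinates come from that match. Unmatched identifiers held at most 0.0146% of reads in a library.

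Groups come from the labels. Counts were tested with edgeR 4.0.16 under R 4.3.3 (TMM scaling, filterByExpr by group with a minimum count of 10, estimateDisp, glmQLFit and glmQLFTest) in one model of 6 group means without covariates, so that each comparison shares an estimate of the spread. Two-sided p-values were adjusted by Benjamini-Hochberg and called under 0.05. Fold changes are on the log2 scale with a standard error derived from the quasi-likelihood F value. The common biological coefficient of variation was 11.0%. Totals of 20910371 to 30368954 reads give the depth, and counting intervals (95%, exact) and floors (3 counts over a group) cover counting error alone. Estimated counts split between near-identical genes and pseudogenes are uncertain, and overlapping or antisense partners cannot be separated without a stated strand setting.

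Gene lists (64, of which 62 had at least 5 tested members) were fixed before the data were examined, as were the designs, the alternatives and the rule for naming genes. That rule took, per comparison, the largest changes with a mean of at least 5 CPM in the higher group and no overlap between libraries, up to 4 members with the smallest adjusted p of each list described, and a panel of 24 genes of which 23 could be tested. Which lists are described in detail was chosen after their results were seen. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), and again with an estimated correlation. Alternatives were another scaling, DESeq2 1.42.0, limma-voom, robust fitting, other count filters, fits of the compared groups alone, a replicate block, effective-length offsets, log2(TPM + 0.1) with limma, leaving out mitochondrially encoded genes, pooled baselines and leaving out each library. Scaling by library totals was added after seeing the data. Library measures were compared with exact two-sided permutation tests. Exact intervals used Python 3.11.15 with scipy 1.17.1.

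The procedure was tested on simulated data with 15732 genes, of which 67, 67 and 66 were changed 1.5-fold, 2-fold and 4-fold. For ISO day 7 against baseline, edgeR recovered 56.7%, 77.6% and 92.4% of them in that order, with 10 false calls. For LPS day 7 against baseline it recovered 62.7%, 79.1% and 97.0%, with 6 false calls. For ISO day 1 it recovered 56.7%, 71.6% and 92.4%, with 13 false calls. For LPS day 1 it recovered 61.2%, 74.6% and 90.9%, with 4 false calls. Far fewer genes were changed in the simulated data than were called at day 1, so error rates under such broad changes were not tested. Apart from the changed genes, simulated libraries shared the same mean per gene, with independent noise. A library that stands apart from its group over many genes was therefore not simulated. The recovery rates need not hold for a group with such a library. No pair of libraries in a group agreed within sampling noise (chi-square per degree of freedom 4.22 to 48.4), so no pair was merged as a library deposited again. Xist stood at 43.1 to 111 CPM and Ddx3y had at most 1 read in each library, and the labels give female mice. Genes assigned to the Y chromosome together held 214 to 2624 reads per library, and the source of these reads was not tested.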

Results

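Poly-A RNA of whole mouse hearts was measured in 23 libraries from female C57BL/6J mice, an inbred laboratory strain, aged 10 weeks. One arm received isoproterenol (ISO), a beta-adrenergic agonist, at 300 mg/kg, and the other received lipopolysaccharide (LPS), a bacterial cell wall component that activates Toll-like receptor 4, at 2.5 mg/kg. Each arm had its own untreated baseline and hearts taken on day 1 and day 7. The ISO day 1 group held 3 libraries and each of the other 5 groups held 4. Estimated reads assigned to genes totalled 20910371 to 30368954 per library, and 15732 genes were tested. The design describes separate mice, so p-values measure the spread between animals together with that of library making.

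Mitochondrially encoded transcripts took 22.3% to 29.3% of reads. Their share was 23.8% ± 1.29 (SD, n = 3) at ISO day 1 against 26.8% ± 1.15 (SD, n = 4) at ISO baseline, and 24.7% ± 1.27 (SD, n = 4) at LPS day 7 against 28.3% ± 0.756 (SD, n = 4) at LPS baseline. Xist, the X-inactivation transcript, stood at 95.6 ± 13.7 CPM (SD, n = 3) at ISO day 1 against 65.5 ± 8.66 CPM (SD, n = 4) at ISO baseline. Genes detected numbered 20672 ± 178 (SD, n = 4) at ISO day 7 against 20194 ± 354 (SD, n = 4) at baseline. The top 10 genes took 25.6% ± 1.68 (SD, n = 3) of reads at ISO day 1 against 29.1% ± 1.05 (SD, n = 4) at ISO baseline, and 27.1% ± 1.24 (SD, n = 4) at LPS day 1 and 27.0% ± 0.866 (SD, n = 4) at LPS day 7 against 29.7% ± 0.767 (SD, n = 4) at LPS baseline. Haemoglobin reads fell to 0.0532% at LPS day 1 from 0.0935% at baseline. In each of these comparisons the two-sided exact permutation test gave p = 0.02857, the smallest these groups allow, and an adjusted p of 0.12 over the 42 library comparisons made.

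**Figure D1:**
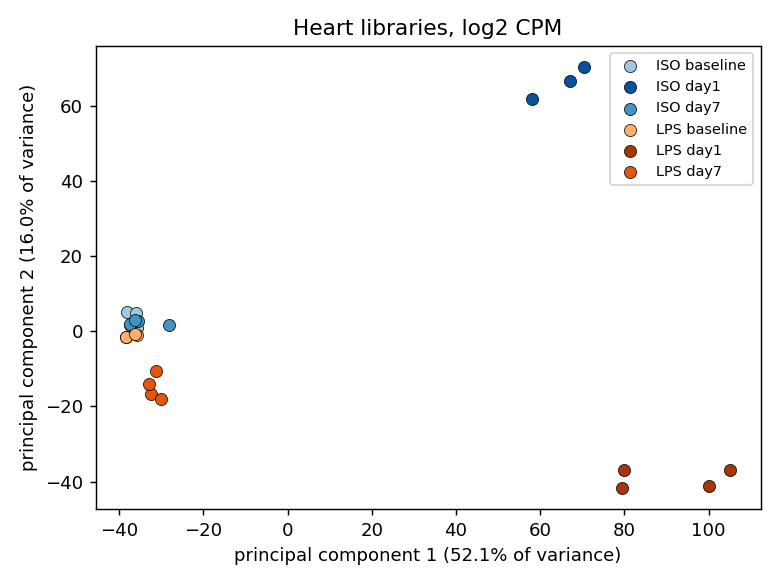
Position of the 23 libraries on the first (horizontal) and second (vertical) principal component of log2 CPM, coloured by group, with 1 point per library. The axes carry 52.1% and 16.0% of the variance, and the day 1 libraries of both arms lie apart from the baseline and day 7 libraries.

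The first comparison asked how the heart transcriptome stood 1 day after isoproterenol. Cardiomyocyte stress genes, acute-phase genes, immediate early genes and ribosomal protein genes were higher than at baseline, and MHC class II, ion channel and branched-chain amino acid catabolism genes were lower. None of these lists kept its call with an estimated correlation between genes (adjusted p = 0.0751 to 0.322 with an estimated correlation). Fhl1, a muscle LIM-domain protein, went from 83.1 ± 1.99 CPM (SD, n = 4) to 2229 ± 223 CPM (SD, n = 3), a log2 change of 4.74 (SE 0.18, adjusted p = 1.94e-15). In all, 10332 genes changed, 5171 higher and 5161 lower, of which 1567 and 2009 changed at least 2-fold. The highest changes by the naming rule included Saa3, an acute-phase serum amyloid (7.72), Nmrk2, a muscle nicotinamide riboside kinase (7.04), Pak3 (6.65) and the metallothionein Mt2 (6.45). Fosl1, an AP-1 subunit, had 2 reads over the baseline group and 769 at day 1, a ratio of 501 with a 95% exact counting interval of 138 to 4142. The lowest included Lsmem1 (-5.27), Col6a6 (-4.76) and Ky (-4.66).

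Of 18 cardiomyocyte stress and fetal-type genes, 16 rose, among them Flnc (3.61) and Actn1 (2.40), and Nppb, the B-type natriuretic peptide gene, rose by 2.13 (SE 0.35), while Myh7 stood at 0.00 (SE 0.28, adjusted p = 0.997). Here and for every list below, counts of members adjusted over the list alone were the same as those over all genes tested unless given. The list passed the camera test (adjusted p = 1.35e-06), but not with an estimated correlation (adjusted p = 0.293 with an estimated correlation). All 23 ribosomal protein genes rose, with a median of 0.76, and immediate early genes rose in 20 of 23, with Nr4a3 at 3.75 (adjusted p = 0.314 with an estimated correlation for each list). All 12 metallothionein and acute-phase genes rose, led by Lcn2 (6.28) and Serpina3n (6.13). Their median was 4.11, or 3.52 with 1 member that had no baseline reads set at its bound and 3.09 with log2(TPM + 0.1) (adjusted p = 0.0751 with an estimated correlation). Heat shock genes rose in 13 of 17 and fell in 2, with Hspa1a at 3.68 and Hspb1 at 3.14 (adjusted p = 0.388 with an estimated correlation). NRF2 antioxidant genes rose in 12 of 19 and fell in 4, with Srxn1 at 3.95 and Gclm at 2.77 (adjusted p = 0.417 with an estimated correlation). Of 22 prosurvival genes 17 rose and 1 fell, including Stat3 (1.80) and Socs3 (3.93), an inhibitor of cytokine signalling (adjusted p = 0.293 with an estimated correlation). No list of the 62 tested in this comparison kept its call with an estimated correlation.

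Branched-chain amino acid catabolism and ion channel genes were lower after isoproterenol. Of 19 genes of branched-chain amino acid catabolism 17 fell and 1 rose, with Mut at -1.23 and Dbt at -1.17 (adjusted p = 0.322 with an estimated correlation). Of 20 ion channel genes 17 fell and 1 rose, with Kcnip2 at -1.87 (adjusted p = 0.293 with an estimated correlation). Interferon-stimulated genes fell in 16 of 24 and rose in 0 (adjusted p = 0.478 with an estimated correlation). MHC class II genes fell in 8 of 9, with H2-Ab1 at -2.79 and H2-Eb1 at -2.73, and B cell genes in 5 of 7, with Ighm at -2.74 (adjusted p = 0.293 with an estimated correlation for each list). Neutrophil genes rose in 10 of 13, and in 11 adjusted over the list alone, with Clec4d at 4.79 (adjusted p = 0.293 with an estimated correlation). Their median was 5.90, or 4.79 with 1 member set at its bound and 2.62 with log2(TPM + 0.1). Haemoglobin reads made up 0.0278% ± 0.0123 (SD, n = 3) of the ISO day 1 libraries against 0.0654% ± 0.0178 (SD, n = 4) at baseline (two-sided exact permutation test, p = 0.05714, adjusted p = 0.185).

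By day 7 after isoproterenol, 1 difference from baseline passed the test. Kcna5 (ENSMUSG00000045534, chromosome 6, 126532551 to 126535412, mm10), a protein-coding voltage-gated potassium channel gene, stood at 20.4 ± 1.79 CPM (SD, n = 4) against 29.9 ± 2.53 CPM (SD, n = 4), a log2 change of -0.55 (SE 0.08, adjusted p = 0.0115). DESeq2 called 2 genes and limma-voom called 1. An unadjusted edgeR p under 0.05 was reached by 863 of 15732 genes, and a share of 0.05 would reach it with no gene changed. The Kcna5 call was lost without ISO baseline replicate 1 (adjusted p = 0.108) or 4 (0.103), without ISO day 7 replicate 1 (0.0892) or 2 (0.0516), with library totals as the scaling (0.533), with the groups fitted alone (0.473) and with log2(TPM + 0.1) (0.617), and its adjusted p ranged from 3.52e-06 to 0.617 over all alternatives. Matrix and fibroblast genes varied between hearts: Postn, periostin, was at 221 CPM in ISO day 7 replicate 3 and at 15.0, 24.1 and 20.2 CPM in the other 3 libraries (log2 change 1.74, SE 0.55, adjusted p = 0.721). Without that library the Postn change was -0.09. Of 16 activated fibroblast genes 0 changed over all genes tested, and 6 were higher adjusted over the list alone (adjusted p = 0.752 with an estimated correlation). The score of that list was 1.60 in ISO day 7 replicate 3 and -0.44, 0.02 and -0.10 in the other 3 libraries. No list kept its call with an estimated correlation.

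LPS on day 1 raised acute-phase genes (adjusted p = 0.00536 with an estimated correlation). Interferon-stimulated, MHC class I and proteasome genes were higher as well (adjusted p = 0.114 to 0.135 with an estimated correlation). All 24 interferon-stimulated genes rose, with a median of 3.71 (adjusted p = 0.135 with an estimated correlation), and Irf7, a transcription factor of the interferon response, rose by 5.49 (SE 0.19, adjusted p = 1.16e-16). Lcn2 (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252, mm10), a protein-coding gene for a neutrophil and acute-phase lipocalin, went from 3.53 ± 1.60 CPM (SD, n = 4) to 2014 ± 281 CPM (SD, n = 4). A total of 10410 genes changed, 5220 higher and 5190 lower, with 1775 and 1949 at least 2-fold. Saa3 (10.93), Gm4841 (9.72) and Gm12250 (8.73) were among the highest by the naming rule. Gm45193 had 0 reads at LPS baseline and 855 at day 1, at least 292-fold higher against a floor of 3 counts over the group. B3galt2 (-5.81), Mgl2 (-5.22) and Spon2 (-4.89) were the lowest by that rule.

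The metallothionein and acute-phase list rose in 12 of 12 members and kept its call (adjusted p = 0.00536 with an estimated correlation), the 1 list of the 62 to do so at LPS day 1. Interferon-gamma and GBP genes rose in 19 of 20, with Iigp1 at 6.13 (adjusted p = 0.0594 with an estimated correlation), and MHC class I genes in 18 of 18, with Psmb10 at 2.94 and Tapbp at 2.48 (adjusted p = 0.114 with an estimated correlation). All 21 proteasome genes rose, led by the activator subunits Psme2 (1.68) and Psme1 (1.35), with an adjusted p = 0.135 with an estimated correlation. Chemokines rose in 15 of 19 and fell in 3, with Cxcl10 at 8.11, Ccl5 at 7.48 and Cxcl12 at -1.66 (adjusted p = 0.181 with an estimated correlation). All 13 neutrophil genes rose, with Hdc at 4.90 (adjusted p = 0.106 with an estimated correlation).

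Several cardiac and resident-cell groups were lower on day 1 of LPS. Ion channel genes fell in 18 of 20 and rose in 2, with Kcnk3 at -1.98 (adjusted p = 0.149 with an estimated correlation). Calcium handling genes fell in 14 of 17 and rose in 2, with Cacnb2 at -2.16 and Pln, phospholamban, at -1.29, and resident macrophage genes fell in 12 of 14 and rose in 2, with Mrc1 at -2.47 (adjusted p = 0.181 with an estimated correlation for each list). Pericyte and smooth muscle genes fell in 12 of 16 and rose in 2, with Notch3 at -1.58 (adjusted p = 0.135 with an estimated correlation). Mitochondrial biogenesis and dynamics genes fell in 13 of 19 and rose in 4, with Esrrg at -2.14 (adjusted p = 0.284 with an estimated correlation). Nppb was at 0.38 (SE 0.32, adjusted p = 0.315). Of 17 heat shock genes 7 rose and 6 fell, and the list missed the threshold (adjusted p = 0.915). The LPS day 1 libraries formed a pair of pairs, with a chi-square per degree of freedom of 14.01 between replicates 1 and 2 and 11.04 between replicates 3 and 4, against 32.08 to 48.45 across them.

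At LPS day 7, natural killer, T cell and MHC genes were above baseline. Gzma (ENSMUSG00000023132, chromosome 13, 113093825 to 113100981, mm10), the protein-coding gene of granzyme A, went from 0.0565 ± 0.0474 CPM (SD, n = 4) to 3.98 ± 0.772 CPM (SD, n = 4), a log2 change of 6.00 (SE 0.42, adjusted p = 1.55e-08). All 9 natural killer genes rose, with a median of 4.77, or 3.11 with log2(TPM + 0.1), and with Il2rb at 3.77 and Nkg7 at 3.86. The list kept its call (adjusted p = 0.000189 with an estimated correlation). Summed over its members, the baseline level was only 0.815 ± 0.09 CPM (SD, n = 4). The size of that median is therefore uncertain. T cell genes rose in 5 of 9, and in 8 adjusted over the list alone, with Lck at 3.31 (adjusted p = 0.00122 with an estimated correlation). MHC class I genes rose in 15 of 18, and in 17 adjusted over the list alone, with H2-K1 at 1.37, and MHC class II genes in 8 of 9 with H2-Ab1 at 0.94 (adjusted p = 0.0456 with an estimated correlation for each list). B cell genes rose in 1 of 7, Ighm, at 0.98, and the median of that list was -0.01, or 0.15 with library totals and 0.27 with log2(TPM + 0.1). Haemoglobin reads made up 0.210% ± 0.165 (SD, n = 4) of the day 7 libraries against 0.0935% ± 0.0198 (SD, n = 4) at baseline (two-sided exact permutation test, p = 0.08571, adjusted p = 0.212), with 0.454% in replicate 2.

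Other groups rose at LPS day 7 without keeping their call. Mitosis genes rose in 22 of 25, and in 23 adjusted over the list alone, with Mki67 and Top2a both at 2.53 (adjusted p = 0.145 with an estimated correlation). General macrophage genes rose in 14 of 17, and in 15 adjusted over the list alone, with Msr1 at 1.41 (adjusted p = 0.13 with an estimated correlation). Interferon-stimulated genes were still higher in 12 of 24, and in 16 adjusted over the list alone, with Irf7 at 2.12 (adjusted p = 0.22 with an estimated correlation).

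In total 1431 genes changed at LPS day 7, 938 higher and 493 lower. Of these, 358 were at least 2-fold higher and 16 at least 2-fold lower. With library totals in place of TMM, the median of all genes moved to 0.16 on the log2 scale and the calls became 2421 higher and 90 lower, and with log2(TPM + 0.1) the median was 0.20 and the calls 2035 higher and 44 lower, so small falls are relative to the TMM scale. On that scale branched-chain amino acid genes fell in 13 of 19, and in 17 adjusted over the list alone (median -0.29, or -0.13 with library totals; adjusted p = 0.149 with an estimated correlation). Nuclear oxidative phosphorylation genes fell in 10 of 26, and in 16 adjusted over the list alone (median -0.23, or -0.07 with library totals; adjusted p = 0.278 with an estimated correlation). Clock genes changed in 10 of 18, 6 higher such as Dbp (1.70) and 4 lower such as Arntl (-1.30), with 8 higher and 6 lower adjusted over the list alone, and the list missed the threshold (adjusted p = 0.209). Against the ISO baseline Dbp stood at 0.44 and Arntl at -0.33, and the median absolute log2 change of the 10 genes went from 0.73 to 0.19. The Arntl call was lost with the baselines of both arms pooled (adjusted p = 0.064) and with log2(TPM + 0.1) (0.0506), and calls of other clock genes were lost with pooled baselines as well. The adjusted p of Arntl lay in a range from 0.00011 to 0.064 among its alternatives. The count of genes was 621 without LPS day 7 replicate 3, 774 without LPS baseline replicate 1, 761 without LPS baseline replicate 2, 2600 with both groups fitted alone and 2242 with pooled baselines.

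**Figure D2:**
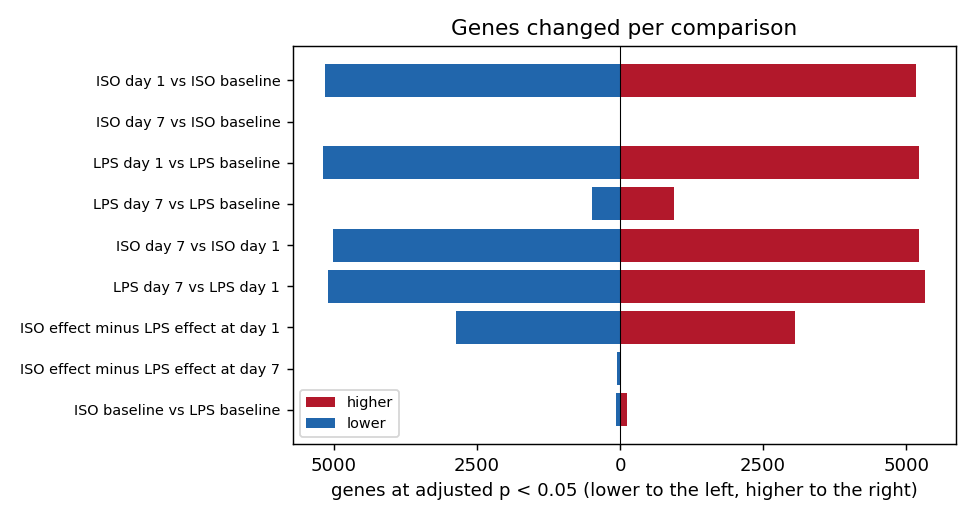
Number of genes at an adjusted p under 0.05 (edgeR), with genes lower in the first group or effect drawn to the left and higher to the right, for each of the 9 comparisons. ISO day 1 and LPS day 1 differed from baseline at 10332 and 10410 genes, ISO day 7 at 1 and LPS day 7 at 1431.

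**Figure D3:**
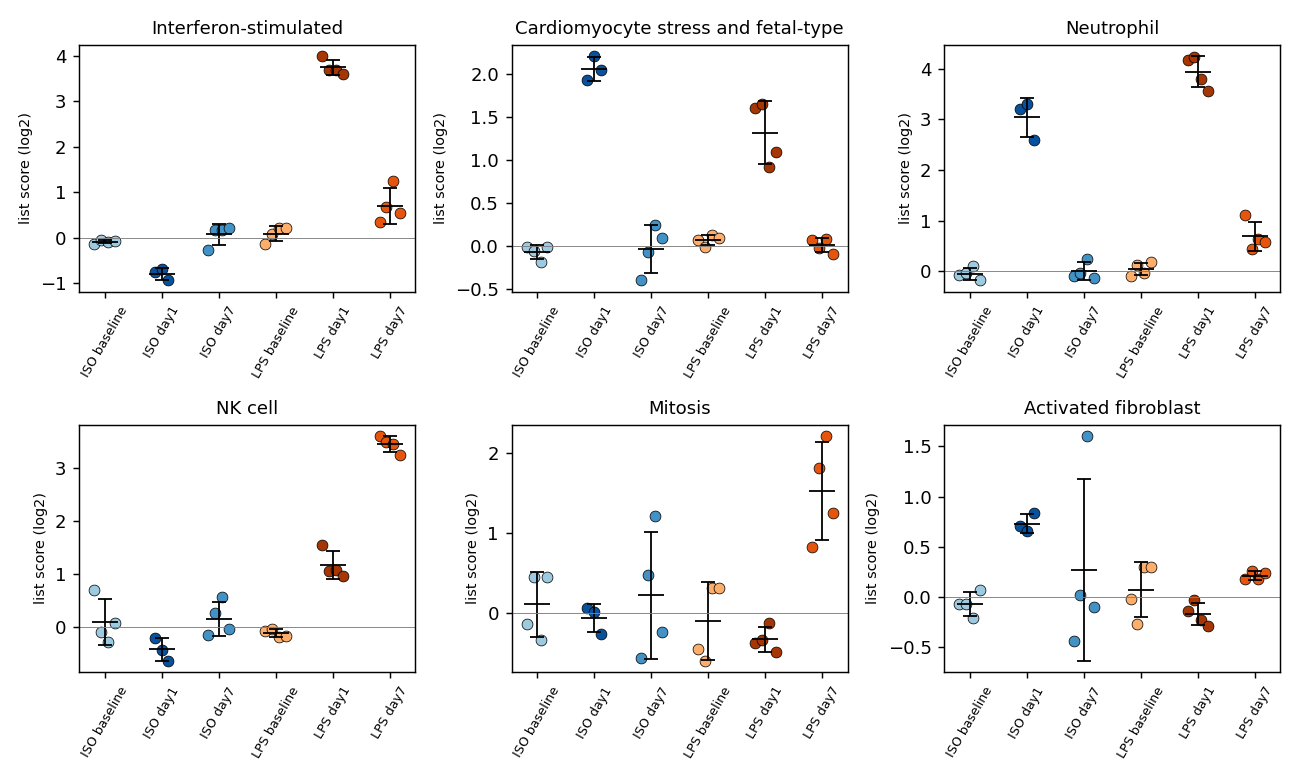
List score of 6 gene lists in each library (vertical axis, mean log2 CPM of the members minus their mean over the baseline libraries) by group (horizontal axis), with black bars for the mean and SD. The natural killer scores at LPS day 7 lie between 3.24 and 3.61, and 1 ISO day 7 library has an activated fibroblast score of 1.60.

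Within each arm, day 7 was compared with day 1. In the ISO arm 10236 genes differed, 5218 higher and 5018 lower at day 7, with Lsmem1 at 5.07 and Nmrk2 at -6.58. In the LPS arm 10444 genes differed, 5336 higher and 5108 lower, and all 24 interferon-stimulated genes were lower at day 7, with Ifit1 at -5.29 (adjusted p = 0.137 with an estimated correlation). The metallothionein and acute-phase genes were lower in 12 of 12 in the LPS arm, with Saa3 at -10.64 (adjusted p = 0.00475 with an estimated correlation). Resident macrophage genes were higher in 12 of 14 and lower in 2 at LPS day 7 than at day 1, with Mrc1 at 3.18 (adjusted p = 0.162 with an estimated correlation). With library totals the LPS split became 6776 higher and 3584 lower as the median of all genes moved to 0.20, and with log2(TPM + 0.1) it became 6463 and 2930 at a median of 0.23. Postn differed between ISO day 7 and ISO day 1 by 0.02 (SE 0.56, adjusted p = 0.979), and by -1.81 (adjusted p = 1.78e-07) without ISO day 7 replicate 3, over a range from 1.78e-07 to 1 among its alternatives.

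Genes called at both days of LPS numbered 749 in the same direction and 232 in opposite directions, where independent lists would share 311.2 higher, 162.6 lower and 473 opposite genes. Both days share the baseline libraries. The covariance of their log2 changes was 0.180 against 0.0478 in 10 simulations of unchanged groups, and 0.148 with the baselines split, while the Pearson correlation was 0.282 against 0.497 in the simulations and 0.194 with the baselines split. For isoproterenol, where 1 gene, Kcna5, was called at both days, these values were 0.0778, 0.0468 and 0.0282 for the covariance and 0.199, 0.473 and 0.054 for the Pearson correlation. No gene changed in the simulations, while 65.7% of genes were called at ISO day 1 and 66.2% at LPS day 1. Such changes widen the spread that scales the Pearson correlation. The simulated Pearson values are therefore no reference, and lower observed ones do not mean less agreement than chance.

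The series title names a comparison of both agents. Among the lists described here, the 2 interferon lists had the largest median differences on day 1. All 24 interferon-stimulated genes had the higher LPS effect, with a list median of -4.74 (adjusted p = 0.0361 with an estimated correlation), and so did all 20 interferon-gamma and GBP genes (median -5.56, adjusted p = 0.00347 with an estimated correlation) and all 18 MHC class I genes (median -2.78, adjusted p = 0.0334 with an estimated correlation). Metallothionein and acute-phase genes had the higher LPS effect in 6 of 12, with Lcn2 at -2.87 (adjusted p = 0.0361 with an estimated correlation). Heat shock genes had the higher ISO effect in 12 of 17 and the higher LPS effect in 2, with Hsph1 at 3.01 (adjusted p = 0.527 with an estimated correlation), and stress and fetal-type genes had the higher ISO effect in 11 of 18 and the higher LPS effect in 1, with Flnc at 3.77 (adjusted p = 0.583 with an estimated correlation). The score of the stress and fetal-type list was 1.61 and 1.65 in LPS day 1 replicates 1 and 2 but 0.92 and 1.09 in replicates 3 and 4, against 1.93 to 2.21 at ISO day 1, so the size of this gap depends on the LPS libraries taken. Nmrk2 (6.84) and Ccl6 (5.56) were among the genes with the highest ISO effect relative to LPS. Mt2, Timp1 and Hmox1 rose in both arms, and their differences did not pass the test (adjusted p = 0.72, 0.823 and 0.459).

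The difference of the effects at day 1 was past the threshold for 5923 genes, 3061 with a higher ISO effect and 2862 with a higher LPS effect. At the same time, 6943 genes were called in the same direction in both arms and 857 in opposite directions. Independent lists of these sizes would share 1715.8 higher and 1702.6 lower genes, and 3468 and 3475 were shared. The arms have separate baselines. The log2 changes correlated across genes (Pearson 0.63, Spearman 0.65), which are not independent replicates.

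At day 7 natural killer genes had the higher LPS effect in 5 of 9, and in 9 adjusted over the list alone, with Il2rb at -3.80 and Nkg7 at -4.66 (adjusted p = 2.98e-05 with an estimated correlation). MHC class II genes did so in 4 of 9, and in 7 adjusted over the list alone, with H2-Eb1 at -1.14 (adjusted p = 0.0292 with an estimated correlation). T cell genes did so in 2 of 9, and in 4 adjusted over the list alone (adjusted p = 0.000195 with an estimated correlation). Those 2 were Lck (-3.31), whose call was lost without ISO baseline replicate 1, 3 or 4, ISO day 7 replicate 1 or 4, LPS baseline replicate 1, 2 or 3 or LPS day 7 replicate 3 (adjusted p = 0.0559 to 0.12) and with effective-length offsets (0.254), and Cd3e (-4.78), whose call was lost without ISO baseline replicate 1, 2 or 3, ISO day 7 replicate 1 or 4 or any LPS baseline replicate (adjusted p = 0.052 to 0.146) and with the replicate block (0.053), effective-length offsets (0.189) and log2(TPM + 0.1) (0.0628). Over all alternatives the adjusted p ranged from 0.0115 to 0.254 for Lck and from 0.0157 to 0.189 for Cd3e. Of 25 mitosis genes 0 differed over all genes tested, and 12 had the higher LPS effect adjusted over the list alone (adjusted p = 0.194 with an estimated correlation). In all the effects differed for 72 genes, 15 with a higher ISO effect and 57 with a higher LPS effect, or 4 and 88 with log2(TPM + 0.1), where the median of all genes was -0.16. The count was 320 without ISO day 7 replicate 3, 40 without ISO baseline replicate 1, 42 without ISO day 7 replicate 4, 46 without LPS baseline replicate 2, 43 without LPS day 7 replicate 3, and 141 with DESeq2.

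The untreated groups of the arms were also compared. Fyb (1.59, adjusted p = 0.000112), an adapter protein of immune cells, and the clock output gene Dbp (1.26, adjusted p = 0.00663) were higher in the ISO arm, and Mroh6 (-1.78, adjusted p = 1.35e-05) was lower. Clock genes were higher in 3 of 18 and lower in 1, with 9 higher and 5 lower adjusted over the list alone, and Nr1d1 stood at 0.63 (list adjusted p = 0.0427, and adjusted p = 0.998 with an estimated correlation). Gm10293 (1.29) and Rps13-ps2 (-1.11) were also called, but a pseudogene such as Rps13-ps2 can share reads with its parent gene. The Rps13-ps2 call was lost without ISO baseline replicate 2 (adjusted p = 0.0512), 3 (0.0734) or 4 (0.0603) or LPS baseline replicate 2 (0.0615), over a range from 0.000176 to 0.0734 among its alternatives. In total 191 genes differed, 116 higher and 75 lower in the ISO arm, or 118 and 129 with log2(TPM + 0.1). The count was 124 without ISO baseline replicate 1, 107 without ISO baseline replicate 2, 124, 119 and 112 without LPS baseline replicate 1, 3 and 4, 701 with both groups fitted alone and 316 with DESeq2. Each baseline belongs to 1 arm, so the arm and any batch between the arms cannot be told apart.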

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

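The tests weighed here were chosen after the results were seen, except the correlation of ISO day 7 replicate 3 with the day 1 fold change and the splits of the libraries. In 455 sets of 4 libraries (library measures, panel genes and list scores), 19 held a library flagged as far from its group. Chance gives about 1 in 20, so 19 is no more than chance alone would give. A flag by itself therefore marks no library as unusual.

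ISO day 7 replicate 3 accounts for 4 of the 19: its Timp1 level was 2.744 on the log2(CPM + 1) scale against 0.878 to 1.038 in the other 3, its general macrophage score 1.131 against -0.196 to -0.006, its heat shock score -0.268 against -0.119 to -0.097, and its Xist level 93.289 CPM against 62.959 to 67.362. Its activated fibroblast score exceeded the mean of the others by 1.78 and its mitosis score by 1.32. A lower cardiomyocyte share would raise endothelial markers as well, and these differed by -0.006 (SD of the other 3, 0.067), which argues against it as the whole cause, but sarcomere genes differed by -0.162 (SD 0.02) and pericyte markers by 0.114 (SD 0.081), so a part of it stays open. Across genes its deviation correlated with the ISO day 1 fold change at a Spearman rho of 0.19, between the bounds set beforehand, and with the LPS day 7 fold change at 0.43. Its activated fibroblast, matrix, general macrophage and mitosis scores exceeded the highest ISO day 1 score by 0.768 or more. For these 4 lists, chosen after the scores were seen, this argues against a remaining day 1 response as the whole cause. Lists raised at ISO day 1 went both ways in replicate 3. Its metallothionein and acute-phase score was 0.516 against -0.161 to 0.082 in the other 3, while its heat shock score lay under theirs. A part of a day 1 response and an untested difference in injury between mice therefore stay open.

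Natural killer and T cell genes were higher at LPS day 7, and the difference from the ISO effect at day 7 passed the test, with median differences of -5.29 (natural killer), -1.881 (T cell) and -0.957 (MHC class II), or -3.248, -0.639 and -1.155 with log2(TPM + 0.1). A lower cardiomyocyte share would raise other resident cells alike, but the highest median among the endothelial, pericyte and fibroblast lists was 0.276 against 4.77 for natural killer genes. Whether blood left in the hearts brought these transcripts cannot be told apart. Summed B cell CPM rose by 10.422 and summed natural killer CPM by 19.9. The B cell rise thus stayed above the bound set for excluding blood and below the one set for blood. From 25.7 CPM at baseline, that B cell rise was 1.405-fold. Ighm was the only B cell gene called at LPS day 7, and the list median was -0.012, or 0.269 with log2(TPM + 0.1). The summed rise is therefore not a rise of the B cell list as a whole. A narrower test, added because the B cell test was undecided, found that the haemoglobin share rose 2.244-fold and natural killer CPM 25.4-fold. The haemoglobin rise did not pass its test (two-sided exact permutation test, p = 0.08571, adjusted p = 0.212). It reached 4.86-fold in replicate 2, the highest of the LPS day 7 libraries. These values argue against more blood of unchanged makeup and leave blood of a changed makeup open. Immune cells in the tissue remain an untested hypothesis.

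Clock genes changed at LPS day 7, and all 10 moved the same way in ISO baseline against LPS baseline, a comparison that shares the LPS baseline. Their median absolute log2 change was 0.734 against the LPS baseline and 0.187 against the ISO baseline, while for all genes called at LPS day 7 the same step went from 0.526 to 0.449. This is consistent with LPS baseline hearts that differ in clock phase, such as by time of collection, which the labels do not give. Whether arm or batch underlies the offset cannot be told apart.

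The effects of the agents differed at 5923 genes on day 1 and 72 on day 7, and on day 1 the list medians differed by -4.743 (interferon-stimulated), -5.556 (interferon-gamma and GBP), -2.775 (MHC class I) and -1.689 (metallothionein and acute-phase). Other libraries far from their group were ISO baseline replicate 2 for genes detected (19669) and Nppa (6.645), LPS baseline replicate 1 for Nppa (6.419), Cd68 (2.164) and the B cell score (0.199), LPS baseline replicate 3 for the clock score (-0.18), and ISO baseline replicate 3 for S100a8 (0.099), Mt2 (3.027) and the recruited monocyte score (-0.222). LPS day 7 held replicate 1 for Myh7 (8.93), replicate 2 for haemoglobin (0.454%), replicate 3 for Hmox1 (3.615) and replicate 4 for the hypertrophy score (-0.035). The remaining ones were LPS day 1 replicate 4 for S100a8 (1.279) and ISO day 7 replicate 1 for the interferon-stimulated score (-0.263). Gene levels are log2(CPM + 1). The S100a8 level of ISO baseline replicate 3 rests on 2 reads, the only ones in that group.

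Other splits of the libraries bear on chance. In each comparison of 2 groups the real split was the 1 of 35 with the most genes. For ISO day 1 the highest other split gave 7539 genes against 10332. It gave 0 against 10410 for LPS day 1 and 0 against 1431 for LPS day 7. Between days it gave 7684 against 10236 in the ISO arm and 1075 against 10444 in the LPS arm. For the baselines it gave 1 against 191. A share of 1 in 35 is the smallest these splits allow, and it was not adjusted over the comparisons. Chance is thus made less likely for these counts but is not excluded. The splits with 7539 and 7684 genes keep the 3 ISO day 1 libraries together with 1 other library. For ISO day 7 the real split gave 1 gene and the others 0. That gene was lost when any 1 of 4 libraries was left out, so chance stays fully open for it. For the differences of effects, 1 of 100 splits, the real one, gave as many genes. The highest other gave 5848 at day 1 and 2 at day 7. At day 1, splits that kept the treated libraries in their groups and regrouped the baselines gave 5570, 5632 and 5848 genes against 5923. The day 1 count thus hardly depended on how the baselines were grouped. At day 7 no other split drawn kept the treated libraries in their groups. Chance is therefore not called excluded for either count.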

How the results depend on the processing

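Scaling by library totals was chosen after seeing the data. All other settings were fixed before. The counts at day 1, those between days and that of the difference at day 1 stayed within 1.5 times under every setting run. ISO day 7 gave 0 genes with library totals, with both groups fitted alone and with log2(TPM + 0.1), 2 without a count filter and with DESeq2, and 3 with pooled baselines. LPS day 7 gave 2511, 2600 and 2242 genes with library totals, the groups alone and pooled baselines. The day 7 difference gave 141 genes with DESeq2, and the baselines differed at 701 genes fitted alone and 316 with DESeq2. The cause was not tested. Leaving out 1 library gave 9426 to 10022 genes for ISO day 1, 0 to 1 for ISO day 7, 9835 to 10236 for LPS day 1, 621 to 1198 for LPS day 7, 9330 to 10131 for ISO day 7 against day 1, 9835 to 10360 for LPS day 7 against day 1, 5181 to 6024 for the day 1 difference, 40 to 320 for the day 7 difference and 107 to 139 for the baselines. Fewer libraries were then fitted.

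Genes changed in the same direction by both agents at day 1 numbered 1993 at 2-fold or more. Those in opposite directions numbered 517 at an adjusted p under 0.01 and 94 at 2-fold. For both agents at day 7 the shared count was 1, then 0 at 0.01, at 2-fold and with the groups alone, and 2 with DESeq2. For ISO days 1 and 7 it was 0 at 0.01, at 2-fold and with the groups alone. For LPS days 1 and 7 the same-direction count was 237, 149 and 1352 and the opposite count 52, 23 and 454 in those 3 settings. Stricter calls leave fewer genes by construction.

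Among genes named, Postn in ISO day 7 against day 1 ranged from -1.81 without ISO day 7 replicate 3 to 0.36 without ISO day 7 replicate 1, and Rplp2 between the baselines went to -0.025 with log2(TPM + 0.1). The cause was not tested. Of 719 named results, called or not, RLE scaling left 719 on the same side of the threshold, with no call reversed. DESeq2 did so for 697, with 1 weaker and 9 stronger, and the rest, Postn among them, had no DESeq2 result. Over all libraries left out, 6429 values of named results stayed the same in this sense, 226 were weaker, 26 stronger and 1 reversed. The replicate block gave 10254, 1, 10415, 1423, 10137, 10426, 5920, 62 and 201 genes in the order of the comparisons above. Same-numbered libraries of an arm correlated at 0.006 on average, 0 of 22 such pairs exceeded 0.1 and 5 of 23 libraries correlated best with their own number, so the numbers were not taken as pairs. Between the arms, same-numbered day 7 libraries exceeded 0.1 for replicate 1 (0.12) and replicate 3 (0.161). Pairs with different numbers exceeded 0.1 between the arms as well, though none of these was between day 7 libraries. Examples were ISO day 7 replicate 1 with LPS baseline replicate 2 (0.155) and ISO day 1 replicate 3 with LPS day 1 replicate 4 (0.141). With the preset correlation 20 lists passed as higher and 11 as lower at ISO day 1, 10 and 12 at ISO day 7, 25 and 12 at LPS day 1 and 23 and 13 at LPS day 7, and 0, 0, 1 and 4 passed with an estimated one. Reads of 20910371 to 30368954 per library limit genes with few counts.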

Other observations

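Other gene groups moved on day 1. After isoproterenol, matrix remodelling genes rose in 15 of 23, and in 16 adjusted over the list alone, and fell in 4, with Mmp3 at 4.31 and Plaur, the urokinase receptor, at 4.97 (adjusted p = 0.314 with an estimated correlation). NF-kB target genes rose in 18 of 22 and fell in 2 after isoproterenol, with Icam1 at 3.98, and rose in 19 of 22 and fell in 1 after LPS, with Icam1 at 3.80 (adjusted p = 0.314 and 0.157 with an estimated correlation). Unfolded protein response genes rose in 16 of 23 and fell in 2 after isoproterenol, with Xbp1 at 1.72 (adjusted p = 0.314 with an estimated correlation). Schwann and neuronal genes fell in 10 of 12 and rose in 2 after LPS, with Stmn2 at -5.26 (adjusted p = 0.135 with an estimated correlation). MHC class II genes fell in 7 of 9 and rose in 1 at LPS day 1, with H2-Aa at -1.66 (adjusted p = 0.294 with an estimated correlation), and stood above baseline at LPS day 7.

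At LPS day 7, complement genes rose in 13 of 18, and in 15 adjusted over the list alone, with Cfb at 2.54 and C3 at 1.39 (adjusted p = 0.0846 with an estimated correlation). Chemokine genes rose in 7 of 19, and in 8 adjusted over the list alone, with Ccl5 at 4.86 (adjusted p = 0.102 with an estimated correlation). The mitochondrial ribosomal RNA genes mt-Rnr1 and mt-Rnr2 stood at -1.15 and -1.01.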
